A study of Rattus norvegicus with 18 samples.

How the data were processed

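RNA of PBMC from 18 rats, 6 per diet, was hybridised to rat 4x44K arrays, 1 rat per array, with the animal's RNA labelled with Cy5 and an equimolar pool of the samples labelled with Cy3, per the labels' protocols. No dye swap is described, so a dye effect common to all arrays cancels in the differences between diets. The authors deposited 1 scanner output per array, made with Agilent Feature Extraction 10.5.1.1 per the submitters' processing notes. Per the file headers, its mean and background-median signals are intensity values per spot on a linear scale, and its processed signals are intensity values after background subtraction, detrending and dye normalization by the scanner software. Spot flags for outliers, saturation and signal well above background are 0 or 1 per the file headers. The authors also deposited a table of log2 values of the same arrays, whose processing is not given in the sources used here. Each of its columns had a median of 8.40, its differences between arrays correlated at 0.971 with those of the log2 ratios (slope 0.992), and it covered 21530 spots of 20256 probes, so its direction and scale could be matched while its centring stays unknown, and it served only as an alternative.

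Each array held 45018 spots, 43379 of them not controls, for 41012 different probes. Signals were background-corrected by normexp with an offset of 50 on the mean and background-median signals, and log2 Cy5/Cy3 ratios were normalized within each array by loess with control spots at weight 0, with no scaling between arrays (R 4.3.3, limma 3.58.1). Spots marked as outliers by the scanner software were set to missing, spots of a probe were averaged, and 25207 probes with Cy5 well above background on at least 5 of 18 arrays were kept. Of all probes, 19459 were well above background on all 18 arrays and 10553 on none. For genes with several probes the brightest was used, which left 21488 genes, 11430 of them with a gene name. Names come from a table of RefSeq genes of assembly GRCr8, to which 21651 of 41012 probes matched by accession, gene ID or symbol, and the file's own name was kept otherwise. That table was used for names only. Probe positions are those of the file headers' design, on rn4, and where a probe lies within its gene was not analysed here. The number of arrays limits the precision.

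The background model was drawn off by marked spots on several arrays, most of all on 4. The normexp model, fitted to all spots as planned before the data were examined, gave a mean Cy5 background of -283 units on LFD replicate 3, -630 on LFD replicate 6, -329 on HFD replicate 4 and -543 on HPD replicate 1, against -5.44 on LFD replicate 1. On those arrays 8, 21, 6 and 3 spots lay far below 0 after subtraction, all of them marked by the scanner software for their local background. The large correction pressed the ratios together: the median absolute deviation of the log2 ratio was 0.055, 0.0144, 0.028 and 0.0123 on the 4 arrays, and 0.153, 0.179, 0.139 and 0.143 when the model was fitted without marked spots. On LFD replicate 4 the mean Cy5 background was -47.6 and the deviation 0.0809 against 0.132. On LFD replicate 5 the deviation was 0.115 against 0.135 and on HFD replicate 5 0.112 against 0.130. The fit as planned was kept as the main result, and the fit without marked spots, chosen after seeing the data, is given wherever it ends a call. Scaling between arrays, which stretches the pressed ratios, and the offset of 10 use the same background model, while the processed signals and the table of log2 values do not.

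Group means were fitted by limma over all 18 arrays with moderated variances, and HFD vs LFD, HPD vs LFD and HPD vs HFD were tested as contrasts, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05, besides a moderated F test for any diet. The array whose labels conflict entered as HPD. Samples enter as separate animals, as the labels describe. The 34 gene lists, 24 of pathways and 10 of cell types, were fixed before the data were examined and tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation, fry, and a two-sided exact permutation test of the per-array list means over 924 splits, whose smallest possible p is 0.00216. Some members belong to more than 1 list, as for 11 of the 18 measured PPAR targets, 7 of 28 fatty acid oxidation genes, 5 of 17 glucocorticoid response genes, 5 of 25 genes of the tricarboxylic acid cycle, 3 of 29 immediate early genes, 2 of 21 monocyte markers and 2 of 16 neutrophil markers, while the erythroid, platelet, T cell, B cell, plasma cell and dendritic cell lists share no measured gene. The rule for named genes took, per comparison, the 5 smallest p per direction among named genes where fewer than that pass. It also took 20 genes fixed beforehand, of which Pdk4 did not pass the filter. From each list that passes it took the 3 members with the smallest p among those in the list's direction. These members were thus picked to go with the shift and add no support to it. Some of the genes this rule takes are not reported here.

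The model was tested on simulated data with 100 genes changed by a log2 difference of 1 and 100 by 2, over 21488 genes. It recovered 97 and 98 of them for HFD vs LFD with 11 false calls, 95 and 99 for HPD vs LFD with 12, and 96 and 99 for HPD vs HFD with 6. A list shifted by 0.5 was found at 0.48 in each comparison, with 0 other lists called. The simulated noise was drawn per gene and so does not carry the correlation between genes that the arrays have. It had the same spread on each array, and the changes were added after background correction. The damping of some arrays by the background model is thus not in the simulation. The recovery is therefore not a measure of the power on the real arrays. Alternatives to the background model, the normalization, the filter on dim probes, the choice of probe, the blocks for slide and replicate number, array weights, covariates for cell composition and the treatment of the conflicting array were also fitted. Of 27 such settings 22 were planned, and so were the 18 fits without each array in turn. Chosen after seeing the data were the 2 background models that leave out marked spots, the fit without slide 1, the fit with HFD replicates 1 and 6 averaged and the exact permutation of list means. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.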

Results

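Gene expression was measured in peripheral blood mononuclear cells (PBMC, the lymphocytes, monocytes and related cells that a density gradient recovers from blood) of 18 male Wistar rats, 6 on each of 3 diets. The low-fat diet (LFD) gave 10% of its energy as fat, 20% as protein and 70% as carbohydrate. The high-fat diet (HFD) gave 60%, 20% and 20%, and the high-protein diet (HPD), with casein as its main protein, gave 10%, 45% and 45%. The rats were 2 months old at the start, ate their diet for 4 months and were fasted for 14 h before blood was taken. HFD and HPD were given in amounts matched in energy to the LFD intake. Each 2-colour array held the Cy5-labelled RNA of 1 rat against a Cy3-labelled pool of the samples. Every value is a log2 ratio of 1 animal to the pool and the diets were compared through it. The median Cy5 signal of a spot was 61.5 to 84.3 intensity units per array over median local backgrounds of 31 to 37. In Cy5, 53.1 to 63.4% of the probes were well above background. The number of arrays limits the precision of each difference, whose median standard error was 0.087 on the log2 scale. The labels of 1 array conflict: its title places it in HFD, as replicate 7, and its source name and description place it in HPD, so it was counted as HPD replicate 7. The arrays were on 5 slides, and slide 1 held 2 LFD and 2 HFD arrays but no HPD array.

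More genes differed between slides than between diets. The first principal component held 29.1% of the variance and the 4 arrays of slide 1 (LFD replicates 1 and 2, HFD replicates 1 and 2) lay at one end of it. The second held 20.5%. With diet in the model, limma called 499 genes for slide and 4621 at an unadjusted p under 0.05. No gene passed limma's test for diet in any comparison or for any diet (0 genes at an adjusted p under 0.05). For any diet, 732 of 21488 genes reached an unadjusted p under 0.05. The correlation between arrays over all probes ranged from -0.48 to 0.67. The labels state the dyes and the reference is a pool of the same samples, so the ratios were kept in the direction Cy5 over Cy3. HFD replicates 1 and 6, on different slides, were the most alike pair (correlation 0.84 over 6238 probes, highest of the other pairs 0.77) and were kept as 2 samples. Averaged as 1 sample in a fit chosen after seeing the data, 2 of the 4 list calls of HFD vs LFD, 10 of 10 of HPD vs LFD and 9 of 14 of HPD vs HFD remained. The averaging leaves the LFD and HPD arrays as they are. The differences of HPD vs LFD could thus not move, and their count says little. The background model damped the log2 ratios of LFD replicates 3 and 6, HFD replicate 4 and HPD replicate 1 most, LFD replicate 4 less and LFD replicate 5 and HFD replicate 5 slightly, where it was drawn off by a few spots with a very bright local background that the scanner software had marked. The calls that end when the model is fitted without the marked spots are named with each comparison. The differences within slides are those of the model as planned. Each LFD array outside slide 1 is one of the damped arrays. Within slides 3, 4 and 5 the LFD side was thus damped, which limits the within-slide values given below. HFD replicate 4 on slide 3 and HPD replicate 1 on slide 2 enter those of HPD vs HFD.

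**Figure D1:**
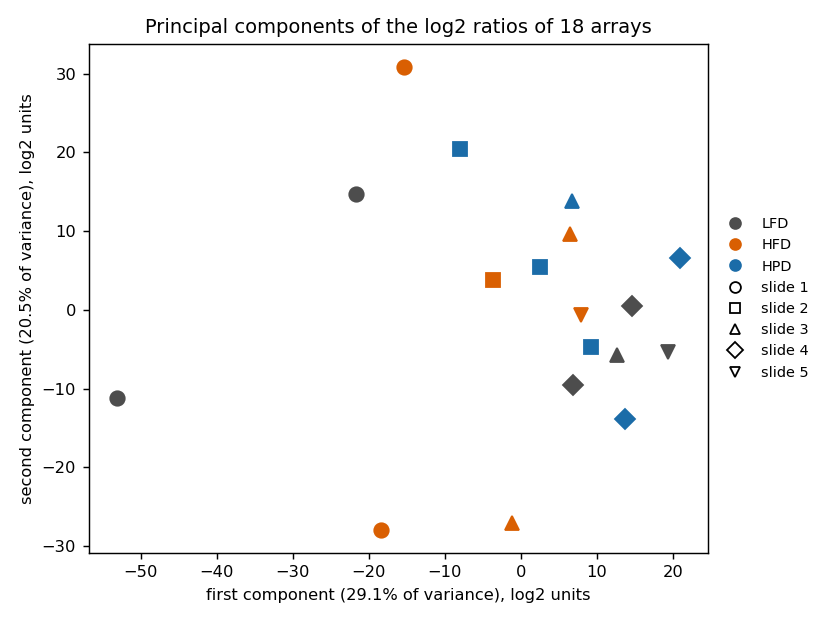
Position of each of the 18 arrays on the first (horizontal) and the second (vertical) principal component of the log2 Cy5/Cy3 ratios, in component units, with colour for the diet and marker shape for the slide. The components hold 29.1% and 20.5% of the variance, and the 4 arrays of slide 1 sit at one end of the first component.

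The first comparison set the high-fat against the low-fat diet, and the 4 gene lists that passed did so with the set test's preset correlation, 0 with an estimated one. Interferon response genes, which restrict virus replication, were lower in HFD than in LFD, with a mean log2 difference of -0.078 (31 of 41 measured members lower, 6 arrays per diet). The members named for this and each later list that passed were those with the smallest p in its direction. The oligoadenylate synthetases Oas1b stood at -0.20 ± 0.10 (log2 difference ± SE) and Oas1i at -0.31 ± 0.16 and the exonuclease Isg20 at -0.14 ± 0.075. T cell markers were lower, with a mean of -0.076 (19 of 24 lower). The surface receptor Cd5 stood at -0.35 ± 0.20 and the T cell receptor signalling proteins Lat at -0.12 ± 0.089 and Zap70 at -0.13 ± 0.11. Immediate early genes, which cells induce within minutes of a stimulus, were higher, with a mean of 0.15 (23 of 29 higher). The transcription factors Egr1 stood at 0.46 ± 0.28, Egr2 at 0.13 ± 0.08 and Klf6 at 0.22 ± 0.14. Plasma cell markers were higher, with a mean of 0.15 (7 of 7 higher). Prdm1, the transcription factor of antibody-secreting cells, stood at 0.28 ± 0.15, the surface proteoglycan Sdc1 at 0.19 ± 0.11 and the transcription factor Irf4 at 0.13 ± 0.081. These 4 of the 34 lists passed camera, limma's set test, with its preset correlation. The adjusted p was 0.00854 for interferon, 0.0385 for T cells, 0.0286 for immediate early genes and 0.0286 for plasma cells. Each had adjusted p = 0.953 with an estimated correlation. Of the HFD arrays, 5 of 6 lay below the LFD mean for interferon genes, 3 for T cells, and 4 and 4 lay above it for immediate early genes and plasma cells. With slide as a block the shifts were -0.081 for interferon, -0.067 for T cells, 0.19 for immediate early genes and 0.13 for plasma cells, all still called. Within slides 1, 3 and 5 (2 against 2, 2 against 1 and 1 against 1 array) they were -0.28, 0.11 and 0.11 for interferon and -0.34, -0.012 and 0.29 for T cells. On the same slides they were 0.27, 0.043 and -0.041 for immediate early genes and 0.39, -0.048 and 0.21 for plasma cells. LFD replicates 3 and 6, the only LFD arrays of slides 3 and 5, were among those that the background model damped most. The interferon call ended without LFD replicate 2, at 0.014, and its shift was -0.13 without LFD replicate 3. The T cell shift was no longer called at -0.037 without LFD replicate 1, -0.047 without LFD replicate 2, -0.064 without LFD replicate 5, -0.028 without HFD replicate 1 and -0.034 without HFD replicate 6. It was called at -0.13 without LFD replicate 6 and -0.12 without HFD replicate 4. The immediate early shift was not called at 0.069 without LFD replicate 2, 0.14 without LFD replicate 6, 0.11 without HFD replicate 1, 0.12 without HFD replicate 3 and 0.12 without HFD replicate 6. The plasma cell shift was not called at 0.11 without LFD replicate 1, 0.11 without LFD replicate 2 and 0.10 without HFD replicate 5. All 4 calls ended with the background model fitted without the marked spots. It gave -0.047 for interferon, -0.039 for T cells, 0.14 for immediate early genes and 0.084 for plasma cells. Without slide 1 the shifts were 0.025 for interferon, 0.055 for T cells, 0.086 for immediate early genes and 0.023 for plasma cells, none of them called.

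The 4 list calls of HFD vs LFD ended under further settings. With the scanner software's processed signals, Cy5 alone, scaling between arrays or array quality weights, 0 of the 4 remained in each. Scaling gave 0.13 for immediate early genes, 0.083 for interferon, -0.013 for plasma cells and 0.28 for T cells, so interferon, T cells and plasma cells changed sign. With HFD replicates 1 and 6 averaged, the values no longer called were 0.12 for immediate early genes and -0.031 for T cells. With the conflicting array counted as HFD, 1 call ended, at 0.059 for immediate early genes. The difference of T cell and monocyte list means as a covariate ended 2, at 0.11 for plasma cells and -0.01 for T cells. The covariate is built from the T cell list itself, so the loss of that call says little. The authors' table of log2 values kept 2, with the others at 0.089 for plasma cells and -0.093 for T cells. Some lists that did not pass in HFD vs LFD did so in some of 23 alternative fits, which leave aside those without each array in turn. NK and cytotoxic cells passed at 0.29 and oxidative phosphorylation at -0.033 without slide 1. Erythroid cells passed at -0.093 and ribosomal proteins at -0.024 with slide as a block. Platelets passed in 3 of the fits, at -0.36 to -0.30.

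Between HFD and LFD, limma called 0 of 21488 genes (lowest adjusted p 1), and 546 reached an unadjusted p under 0.05 (257 higher, 289 lower in HFD) where chance gives 1074.4. The smallest p belonged to Lrwd1, which binds the origin recognition complex, at -0.36 ± 0.087 (unadjusted p 0.000596; probe on chromosome 12, 21648642 to 21649113, rat assembly rn4). Lag3, an inhibitory receptor of activated T cells, stood at -0.36 ± 0.093 (chromosome 4, 161036255 to 161036314). Acbd4 stood at -0.21 ± 0.055, Psd4 at -0.25 ± 0.071 and Tmcc2 at -0.66 ± 0.19. Among genes with higher values, Tceal9 stood at 0.55 ± 0.16, Ndel1 at 0.21 ± 0.071, Luc7l2 at 0.18 ± 0.062, the sodium pump subunit Atp1b3 at 0.16 ± 0.05 and the metalloreductase Steap4 at 0.15 ± 0.049. No list member passed over all genes, and 0 passed adjusted over the list alone. Among the lists that did not pass, the mean log2 differences above 0 were 0.15 for monocytes, 0.11 for neutrophils, 0.11 for glucocorticoid response, 0.075 for B cells, 0.072 for cytosolic heat shock proteins, 0.072 for NF-kB and inflammatory mediators, 0.053 for PPAR targets, 0.05 for NK and cytotoxic cells, 0.05 for apoptosis and p53 and 0.047 for ER chaperones and unfolded protein response. They were 0.046 for fatty acid oxidation, 0.041 for circadian clock, 0.035 for dendritic cells, 0.032 for cholesterol synthesis, 0.021 for basophils, mast cells and eosinophils, 0.014 for tricarboxylic acid cycle, 0.01 for lipid droplets, uptake and efflux, 0.006 for glycolysis and 0.001 for the NRF2 antioxidant response. Those below 0 were -0.18 for platelets, -0.10 for MHC class II presentation, -0.046 for amino acid and urea catabolism, -0.024 for lipogenesis, -0.016 for oxidative phosphorylation and -0.014 for cytosolic ribosomal proteins. They were -0.011 for erythroid cells, -0.01 for the ATF4 amino acid response, -0.008 for proteasome, -0.006 for insulin and adipokine signalling and -0.004 for cell cycle. The MHC class II mean rests on RT1-Bb, whose arrays fall into 2 parts, at -1.45, and a mean over the other 14 members, taken after seeing the data, was 0.002. In the glycolysis list the arrays of Ldhb fall into 2 parts, with 4 LFD and 1 HFD arrays in the low one, and a mean without it was not taken. The lowest adjusted p among the lists that did not pass was 0.0848, for monocytes. For the NRF2 antioxidant response, erythroid cells, glycolysis, insulin and adipokine signalling, lipid droplets, MHC class II presentation and the tricarboxylic acid cycle, 7 lists in all, the mean, the median and the set test differed in sign. Tests over whole arrays gave no call, with a lowest adjusted p of 0.957 by fry and 0.971 by exact permutation of the per-array list means.

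The second comparison set the high-protein diet, with protein in place of part of the carbohydrate, against the low-fat diet with the same share of fat. Of the 10 cell type lists, 4 passed camera with its preset correlation and 0 with an estimated one. Markers of red cell precursors and reticulocytes were lower in HPD than in LFD, with a mean log2 difference of -0.36 (27 of 30 members lower, 6 of 6 HPD arrays below the LFD mean). The red cell anion exchanger Slc4a1 stood at -1.05 ± 0.48, the membrane skeleton protein Add2 at -0.92 ± 0.35 and Fech, the last enzyme of haem synthesis, at -0.68 ± 0.30. Platelet markers were lower, with a mean of -0.45 (20 of 21 members, 6 of 6 arrays). The integrin subunit Itga2b stood at -0.70 ± 0.42, the coagulation factor XIII subunit F13a1 at -0.82 ± 0.45 and Nrgn at -0.50 ± 0.27. Without LFD replicate 2, F13a1 HPD vs LFD stood at -0.37. NK and cytotoxic cell markers were lower, with a mean of -0.20 (18 of 20 members, 5 of 6 arrays). Perforin (Prf1) stood at -0.33 ± 0.21, the receptor Klrb1b at -0.30 ± 0.21 and the transcription factor Eomes at -0.15 ± 0.083. Monocyte markers were lower, with a mean of -0.21 (18 of 21 members, 5 of 6 arrays). Lysozyme (Lyz2) stood at -0.59 ± 0.40 and the phagosomal metal transporter Slc11a1 at -0.41 ± 0.29. The proteoglycan gene Vcan was well above background on 5 of 6 LFD and 2 of 6 HPD arrays, too few to give a difference. With the preset correlation the adjusted p was 1.83e-08 for erythroid cells, 3.26e-05 for platelets, 0.00134 for NK cells and 0.00374 for monocytes. With an estimated correlation the adjusted p was 0.373 for erythroid cells, 0.582 for platelets and 0.608 for both NK cells and monocytes. With slide as a block the shifts were -0.38 for erythroid cells and -0.36 for platelets, still called. They were -0.10 for NK cells and -0.17 for monocytes, no longer called. Within slides 3 and 4 (1 against 1 and 2 against 2 arrays) they were -0.93 and -0.051 for erythroid cells and -0.35 and -0.049 for platelets. On these slides they were 0.23 and -0.14 for NK cells and -0.46 and -0.28 for monocytes. The monocyte call ended without HPD replicate 4, at -0.068, and the NK call without LFD replicate 1, at -0.074. The NK shift was -0.10 without LFD replicate 2 and -0.32 without LFD replicate 5 and the platelet shift -0.25 without LFD replicate 2. The NK shift was above 0, at 0.086, without slide 1, and the erythroid shift was -0.21 there.

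Of the 24 pathway lists, 6 passed camera with its preset correlation between HPD and LFD, each of them lower in HPD, and 0 passed with an estimated correlation. NRF2 antioxidant response genes had a mean log2 difference of -0.14 (21 of 24 lower). Glutathione reductase (Gsr) stood at -0.46 ± 0.21, transketolase (Tkt) at -0.31 ± 0.15 and the ferritin heavy chain (Fth1) at -0.65 ± 0.38. Without LFD replicate 2, Gsr HPD vs LFD stood at -0.23. Glycolysis genes had a mean of -0.10 (16 of 26 lower). Hexokinase 1 (Hk1) stood at -0.41 ± 0.17, Eno1 at -0.29 ± 0.14 and Tpi1 at -0.27 ± 0.12. Insulin and adipokine signalling genes had a mean of -0.11 (15 of 23 lower). The glucose transporter Slc2a4 stood at -0.78 ± 0.36, the kinases Akt2 at -0.21 ± 0.089 and Mtor at -0.19 ± 0.08. Genes of lipid droplets and lipid uptake and efflux had a mean of -0.10 (17 of 21 lower). Plin3, a lipid droplet coat protein, stood at -0.28 ± 0.13, the triglyceride lipase Pnpla2 at -0.24 ± 0.10 and the lysosomal cholesterol carrier Npc2 at -0.21 ± 0.094. NF-kB and inflammatory mediators had a mean of -0.13 (25 of 34 lower). The chemokine Ccl2 stood at -0.65 ± 0.25, the adaptor Myd88 at -0.38 ± 0.18 and Nfkbie at -0.25 ± 0.13. Immediate early genes had a mean of -0.10 (22 of 29 lower). Ier2 stood at -0.31 ± 0.17, Fosl2 at -0.27 ± 0.15 and Csrnp1 at -0.18 ± 0.11. Camera's preset correlation gave adjusted p 0.00374 for NRF2, 0.00779 for lipid droplets and 0.0083 for NF-kB. It gave 0.0123 for insulin signalling, 0.0139 for glycolysis and 0.0417 for immediate early genes. With an estimated correlation the adjusted p was 0.46 for NRF2 and for NF-kB, 0.373 for lipid droplets, insulin signalling and glycolysis, and 0.792 for immediate early genes. The slide-blocked shifts, all still called, were -0.12 for NRF2, -0.12 for lipid droplets and -0.15 for NF-kB. They were -0.10 for insulin signalling, -0.12 for glycolysis and -0.13 for immediate early genes. Within slides 3 and 4 they were -0.22 and -0.073 for NRF2, -0.23 and -0.16 for lipid droplets and -0.33 and -0.093 for NF-kB. There they were -0.15 and 0.001 for insulin signalling, -0.18 and -0.042 for glycolysis and -0.28 and 0.031 for immediate early genes. Without HPD replicate 4 the calls ended for NRF2 at -0.11, glycolysis at -0.077, lipid droplets at -0.049 and NF-kB at -0.075. The immediate early shift was not called at -0.047 without LFD replicate 1, -0.085 without LFD replicate 3, -0.08 without LFD replicate 5, -0.11 without LFD replicate 6, -0.026 without HPD replicate 7, -0.08 without HPD replicate 4 and -0.077 without HPD replicate 5. It was called at -0.18 without LFD replicate 2 and -0.19 without HPD replicate 2. NRF2 stood at -0.087 without LFD replicate 2 and NF-kB at -0.21 without HPD replicate 2, both called. The insulin signalling call ended with the background model fitted without the marked spots, at -0.10.

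Of the 10 list calls of HPD vs LFD, 4 remained with each array's erythroid list mean as a covariate. Besides the erythroid list itself, which this covariate sets to 0, the values no longer called were -0.081 for NRF2, -0.014 for immediate early genes, -0.081 for insulin signalling, -0.12 for monocytes and -0.046 for NK cells. With the difference of T cell and monocyte list means as a covariate 4 remained, and the others stood at -0.086 for NRF2, -0.072 for glycolysis, -0.082 for immediate early genes, -0.06 for lipid droplets, -0.073 for monocytes and -0.078 for NF-kB. That covariate is built from the monocyte list itself, so the loss of the monocyte call says little. The fit without slide 1 kept 7, and the others stood at -0.062 for glycolysis, -0.08 for insulin signalling and 0.086 for NK cells. Cy5 alone kept 6, with the others at -0.078 for NRF2, -0.047 for immediate early genes, -0.088 for insulin signalling and -0.11 for NF-kB. Scaling between arrays kept 7, with the others at -0.014 for glycolysis, -0.065 for immediate early genes and -0.079 for insulin signalling. Array quality weights kept 8, with the others at -0.081 for insulin signalling and -0.039 for NK cells. With the conflicting array counted as HFD 9 remained, and immediate early genes stood at -0.026. The authors' table of log2 values kept 10 of 10. Lists that did not pass in HPD vs LFD did so in some of the 23 alternative fits. MHC class II presentation, where RT1-Bb carries much of the mean, passed in 7 of them, at -0.80 to -0.22, and ribosomal proteins in 5, at 0.05 to 0.16. The interferon response passed in 2 with a sign opposite to its planned value, at 0.10 without slide 1 and 0.21 with scaling. T cells passed with scaling alone, at 0.46.

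**Figure D2:**
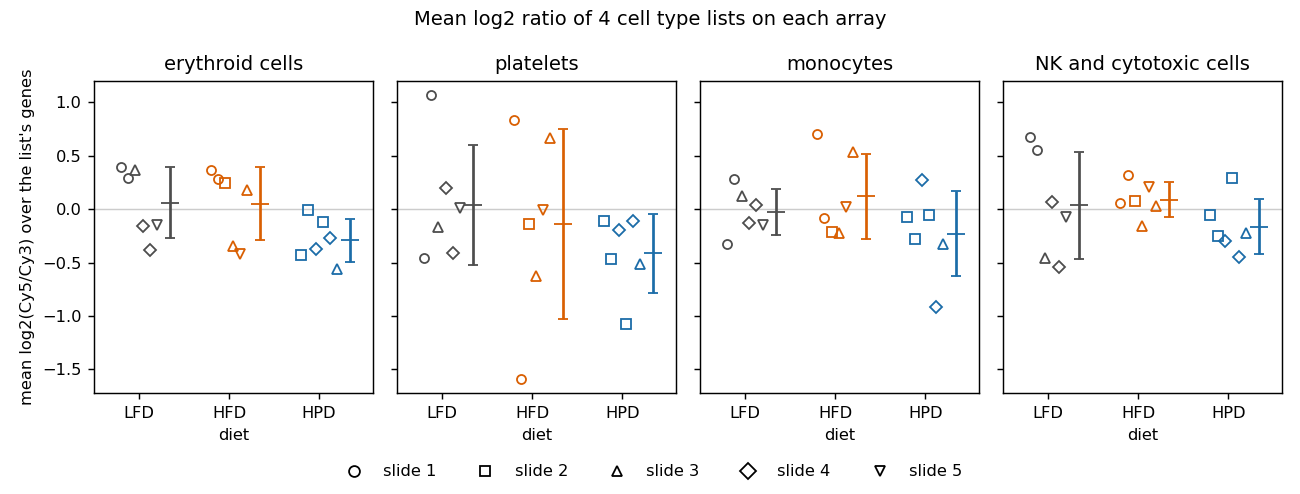
Mean log2 Cy5/Cy3 ratio of the erythroid, platelet, monocyte and NK and cytotoxic cell lists in each array (vertical axes), by diet (horizontal axes), with 1 point per array, marker shape for the slide and a bar for the mean ± SD of 6 arrays. The HPD mean lies below the LFD mean, at differences of -0.36 for erythroid cells, -0.45 for platelets, -0.20 for NK cells and -0.21 for monocytes.

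Limma called 0 of 21488 genes between HPD and LFD (lowest adjusted p 0.829), and 1155 reached an unadjusted p under 0.05 (698 higher, 457 lower in HPD) where chance gives 1074.4. That count moved with the processing. It was 617 with the background model fitted without the marked spots, 635 with the processed signals and 525 with scaling between arrays. It was 1518 with a replicate block and 1647 with array quality weights. The smallest p among named genes belonged to Kif19, a kinesin motor, at 1.1 ± 0.23 (unadjusted p 0.000148; HPD 0.48 ± 0.36, LFD -0.62 ± 0.49, SD; limma, chromosome 10, 104671675 to 104672841, rn4). Zdhhc22 stood at 0.86 ± 0.20, the RNA-binding protein gene Rbm38 at 0.82 ± 0.19 and Thpol1 at 0.21 ± 0.05. Togaram1 stood at 0.35 ± 0.08, and its other probe gave -0.006. Lower values were measured for the Arp2/3 complex subunit Arpc4 at -0.30 ± 0.078, Zmym3 at -0.30 ± 0.071 and Klhl17 at -0.25 ± 0.067. No list member passed over all genes, and 0 passed adjusted over the list alone. Among the lists that did not pass, the mean log2 differences above 0 were 0.076 for plasma cells, 0.035 for B cells, 0.032 for cytosolic ribosomal proteins, 0.029 for cell cycle and 0.011 for fatty acid oxidation. They were 0.008 for cholesterol synthesis, 0.004 for proteasome, 0.003 for oxidative phosphorylation and 0.001 for tricarboxylic acid cycle. Those below 0 were -0.21 for MHC class II presentation, -0.083 for glucocorticoid response, -0.082 for dendritic cells, -0.072 for the ATF4 amino acid response, -0.06 for lipogenesis, -0.056 for ER chaperones and unfolded protein response, -0.042 for amino acid and urea catabolism and -0.039 for neutrophils. They were -0.035 for PPAR targets, -0.034 for interferon response, -0.024 for circadian clock, -0.023 for apoptosis and p53, -0.019 for T cells, -0.008 for cytosolic heat shock proteins and -0.003 for basophils, mast cells and eosinophils. In the MHC class II list RT1-Bb stood at -2.12, and the other 14 members had a mean of -0.077. The lowest adjusted p among them was 0.0563, for the ATF4 amino acid response. The mean, the median and the set test differed in sign for 4 lists, namely basophils with mast cells and eosinophils, cholesterol synthesis, fatty acid oxidation and neutrophils. Tests over whole arrays gave no call, with a lowest adjusted p of 0.716 by fry and 0.696 by exact permutation. The erythroid list had an unadjusted exact permutation p of 0.0584.

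The third comparison set the high-protein against the high-fat diet, and 6 of the 10 cell type lists passed camera with its preset correlation, 0 with an estimated one. Monocyte markers were lower in HPD than in HFD, with a mean log2 difference of -0.35 (20 of 21 members lower, 5 of 6 HPD arrays below the HFD mean). The lipopolysaccharide receptor Cd14 stood at -1.17 ± 0.37 and Nr4a1 at -0.59 ± 0.24, while Vcan was well above background on 5 of 6 HFD and 2 of 6 HPD arrays, too few to give a difference. Erythroid markers were lower, with a mean of -0.34 (28 of 30 members, 6 of 6 arrays). Add2 stood at -0.91 ± 0.35, Fech at -0.74 ± 0.30 and the membrane protein Epb42 at -0.55 ± 0.21. NK and cytotoxic cell markers were lower, with a mean of -0.25 (19 of 20 members, 5 of 6 arrays). The receptors Klrb1b stood at -0.60 ± 0.21 and Ncr1 at -0.54 ± 0.33 and granzyme K (Gzmk) at -0.46 ± 0.24. Platelet markers had a mean of -0.27 (20 of 21 lower). F13a1 stood at -0.59 ± 0.45, Cd9 at -0.39 ± 0.33 and Sparc at -0.20 ± 0.15. Neutrophil markers had a mean of -0.15 (11 of 16 lower). The ficolin Fcnb stood at -1.13 ± 0.41, the G-CSF receptor Csf3r at -0.33 ± 0.12 and Trem1 at -0.24 ± 0.12. Dendritic cell markers had a mean of -0.12 (8 of 10 lower). The transcription factors Irf8 stood at -0.35 ± 0.16 and Tcf4 at -0.27 ± 0.15 and the lectin Clec10a at -0.31 ± 0.13. Camera's preset correlation gave adjusted p 4.02e-07 for monocytes and for erythroid cells and 9.49e-05 for NK cells. It gave 0.00895 for platelets, 0.0147 for neutrophils and 0.0308 for dendritic cells. With an estimated correlation the adjusted p was 0.282 for monocytes, erythroid cells, neutrophils and dendritic cells, 0.484 for NK cells and 0.629 for platelets. With slide as a block the shifts of monocytes (-0.29), erythroid cells (-0.29) and neutrophils (-0.17) were still called. Those of NK cells (-0.078), platelets (-0.21) and dendritic cells (-0.11) were not. Within slides 2 and 3 (3 against 1 and 1 against 2 arrays) they were 0.081 and -0.49 for monocytes, -0.43 and -0.47 for erythroid cells and -0.085 and -0.16 for NK cells. They were -0.41 and -0.54 for platelets, -0.009 and -0.24 for neutrophils and -0.074 and -0.19 for dendritic cells. The platelet shift was not called at -0.074 without HFD replicate 1, -0.11 without HFD replicate 6 and -0.14 without HPD replicate 3. It was called at -0.56 without HFD replicate 2. The neutrophil shift was not called at -0.11 without HFD replicate 1, -0.11 without HFD replicate 6 and -0.10 without HPD replicate 4. The dendritic cell shift was not called at -0.093 without HFD replicate 1, -0.12 without HFD replicate 2, -0.10 without HFD replicate 6, -0.094 without HPD replicate 4 and -0.10 without HPD replicate 5. The monocyte shift was -0.22 without HPD replicate 4, still called. The monocyte list mean was 0.70 and 0.53 on HFD replicates 1 and 6, the most alike pair of arrays. On the other HFD arrays it was -0.22 to 0.023, also below the HFD mean of 0.12. It was -0.92 on HPD replicate 4 and -0.33 to 0.28 on the other HPD arrays. The shift thus rests largely on these few arrays, and no fit left them out together. The neutrophil call ended with the background model fitted without the marked spots, at -0.13.

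Between HPD and HFD, 8 of the 24 pathway lists passed camera with its preset correlation, 7 of them lower and 1 higher in HPD, and 0 passed with an estimated correlation. Immediate early genes had a mean log2 difference of -0.25 (26 of 29 lower). Nr4a1 stood at -0.59 ± 0.24, Fos at -0.56 ± 0.25 and Ier2 at -0.49 ± 0.17. NF-kB and inflammatory mediators had a mean of -0.20 (26 of 34 lower). The chemokines Cxcl2 stood at -1.85 ± 0.79 and Ccl2 at -0.66 ± 0.25 and interferon gamma (Ifng) at -0.57 ± 0.24. The arrays of Cxcl2 fall into 2 parts, with 0 HFD and 3 HPD arrays in the low one. It thus weighs on the list mean, and a mean without it was not taken. Glucocorticoid response genes had a mean of -0.19 (16 of 17 lower). The phosphatase Dusp1 stood at -0.69 ± 0.32, Ddit4 at -0.29 ± 0.21 and annexin A1 (Anxa1) at -0.20 ± 0.13. ER chaperones had a mean of -0.10 (23 of 25 lower). Dnajc3 stood at -0.29 ± 0.14, the stress sensor Atf6 at -0.21 ± 0.12 and Dnajb11 at -0.17 ± 0.094. NRF2 genes had a mean of -0.14 (18 of 24 lower). Catalase (Cat) stood at -0.34 ± 0.18, Tkt at -0.26 ± 0.15 and Taldo1 at -0.19 ± 0.10. Insulin and adipokine signalling stood at -0.10 (16 of 23 lower). The adiponectin receptor Adipor1 stood at -0.23 ± 0.13, Pik3r1 at -0.22 ± 0.11 and Mtor at -0.15 ± 0.08. Lipid droplets, uptake and efflux stood at -0.11 (16 of 21 lower). Lrp1 stood at -0.47 ± 0.23, Npc2 at -0.29 ± 0.094 and the cholesterol exporter Abca1 at -0.20 ± 0.10. Cytosolic ribosomal protein genes were higher, with a mean of 0.046 (53 of 73 higher). Rpl37a stood at 0.19 ± 0.087, Rpl13 at 0.16 ± 0.081 and Rpl22 at 0.15 ± 0.079. Camera's preset correlation gave adjusted p 4.74e-06 for immediate early genes, 0.00578 for NF-kB and 0.00895 for glucocorticoid response and NRF2. It gave 0.00872 for insulin signalling, 0.0122 for ER chaperones, 0.0147 for lipid droplets and 0.0161 for ribosomal proteins. With an estimated correlation the adjusted p was 0.4 for NRF2, 0.629 for ribosomal proteins and 0.282 for the other 6 of these lists. With slide as a block the shifts of immediate early genes (-0.32), NF-kB (-0.24), glucocorticoid response (-0.24), insulin signalling (-0.11) and lipid droplets (-0.13) were still called. Those of NRF2 (-0.11), ER chaperones (-0.051) and ribosomal proteins (0.032) were not. Within slides 2 and 3 they were -0.48 and -0.33 for immediate early genes, -0.22 and -0.31 for NF-kB and -0.36 and -0.24 for glucocorticoid response. They were -0.11 and -0.048 for ER chaperones, -0.078 and -0.20 for NRF2, -0.18 and -0.18 for insulin signalling, 0.033 and -0.23 for lipid droplets and 0.013 and 0.027 for ribosomal proteins. The ribosomal shift was not called at 0.016 without HFD replicate 1, 0.033 without HFD replicate 2, 0.027 without HFD replicate 6, 0.04 without HPD replicate 1, 0.017 without HPD replicate 4 and 0.037 without HPD replicate 5. It was called at 0.091 without HFD replicate 4. NRF2 was not called at -0.08 without HFD replicate 1, -0.094 without HFD replicate 6 and -0.11 without HPD replicate 4, ER chaperones at -0.081 without HFD replicate 2 and -0.085 without HPD replicate 4 and lipid droplets at -0.059 without HPD replicate 4 and -0.085 without HPD replicate 5. The glucocorticoid call ended at -0.13 without HPD replicate 7, the array with conflicting labels, and the NF-kB call at -0.15 without HPD replicate 4.

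Of the 14 list calls of HPD vs HFD, 5 remained with each array's erythroid list mean as a covariate, while 9 lists passed in all. Besides the erythroid list, set to 0, the values no longer called were -0.083 for NRF2, 0.002 for ribosomal proteins, -0.091 for dendritic cells, -0.043 for ER chaperones, -0.12 for glucocorticoid response, -0.075 for insulin signalling, -0.084 for neutrophils and -0.10 for NK cells. With the difference of T cell and monocyte list means as a covariate 6 remained and 1 changed sign, with the others at -0.022 for NRF2, -0.014 for ribosomal proteins, -0.065 for dendritic cells, -0.024 for lipid droplets, -0.064 for monocytes, -0.05 for neutrophils, -0.09 for NF-kB and -0.006 for platelets. As this covariate is built from the monocyte list, the loss of the monocyte call says little. With the conflicting array counted as HFD 9 remained. The others stood at -0.10 for dendritic cells, -0.054 for ER chaperones, -0.052 for glucocorticoid response, -0.085 for immediate early genes and -0.07 for insulin signalling. With HFD replicates 1 and 6 averaged 9 remained, and the others stood at -0.087 for NRF2, 0.021 for ribosomal proteins, -0.10 for dendritic cells, -0.11 for neutrophils and -0.091 for platelets. The fit without slide 1 kept 10, and the others stood at -0.008 for ribosomal proteins, -0.088 for dendritic cells, -0.063 for ER chaperones and -0.079 for neutrophils. Scaling between arrays kept 7, with the others at 0.079 for ribosomal proteins, -0.10 for dendritic cells, -0.10 for ER chaperones, -0.062 for erythroid cells, -0.16 for glucocorticoid response, -0.074 for insulin signalling and -0.052 for neutrophils. Cy5 alone kept 11, with the others at -0.061 for NRF2, -0.09 for dendritic cells and -0.091 for neutrophils. Array quality weights kept 11, with the others at 0.014 for ribosomal proteins, -0.089 for dendritic cells and -0.10 for neutrophils. The processed signals kept 13, with neutrophils at -0.23. The authors' table of log2 values kept 13, with -0.044 for NRF2. Lists that did not pass in HPD vs HFD did so in some of the 23 alternative fits. The interferon response passed in 16 of them, at 0.048 to 0.15, among them 0.11 with slide as a block and 0.055 with the background model fitted without the marked spots. The circadian clock passed in 8, at -0.14 to -0.037, cytosolic heat shock proteins in 8, at -0.17 to -0.075, and oxidative phosphorylation in 6, at 0.027 to 0.16.

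**Figure D3:**
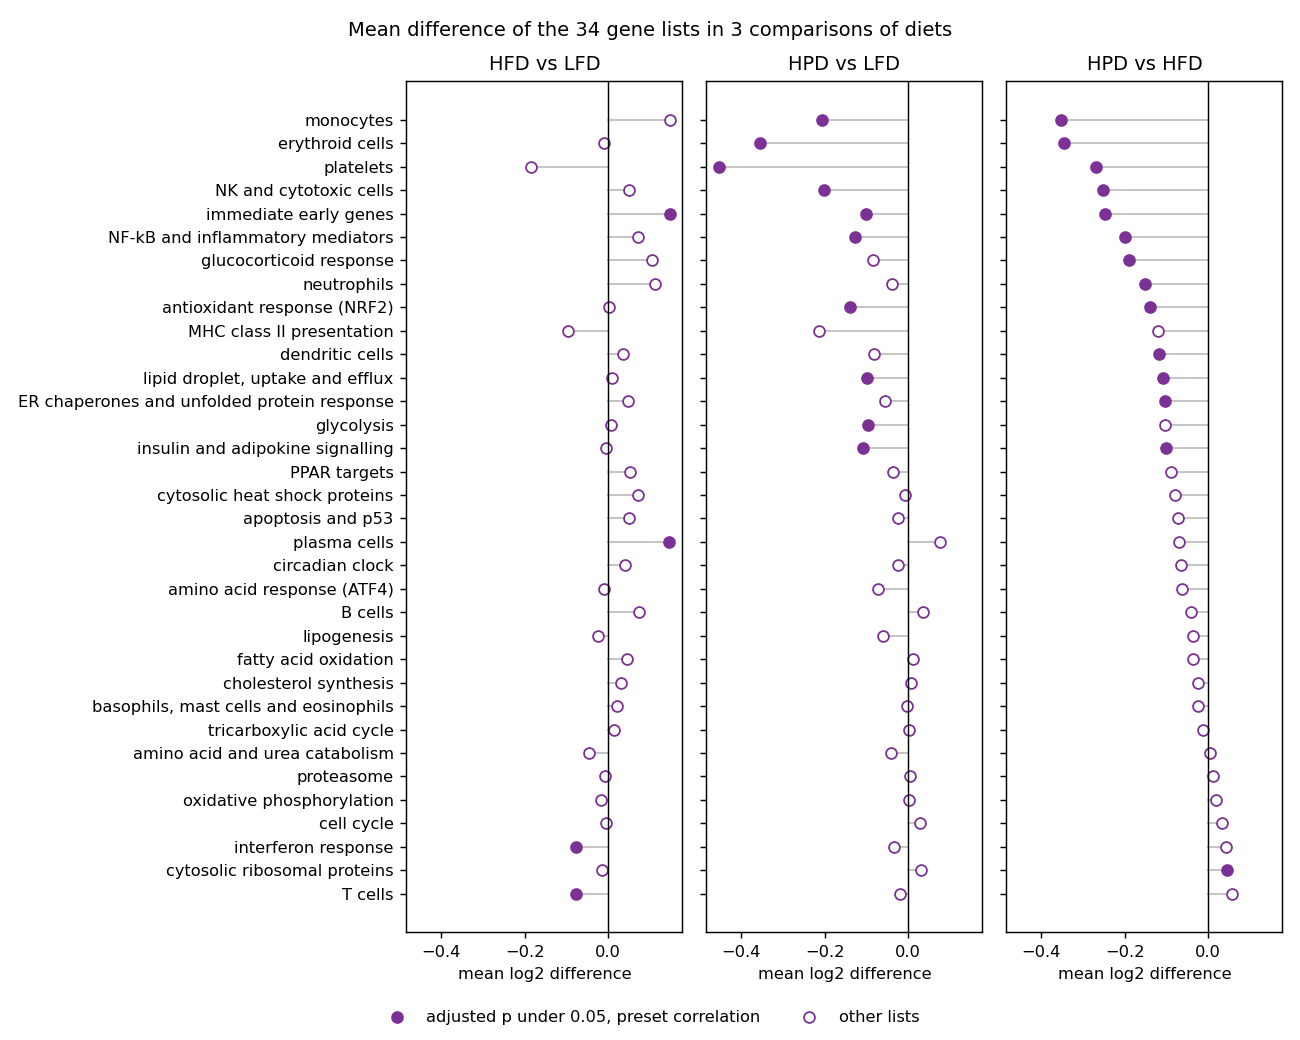
Mean log2 difference over the measured members of each of the 34 gene lists (vertical axis) in the 3 comparisons (horizontal axis, log2 units), with 1 point per list and comparison, filled where camera with a preset correlation gave an adjusted p under 0.05. The filled points number 4 for HFD vs LFD, 10 for HPD vs LFD and 14 for HPD vs HFD, and 0 in each with an estimated correlation.

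Limma called 0 of 21488 genes between HPD and HFD (lowest adjusted p 0.895), and 904 reached an unadjusted p under 0.05 (508 higher, 396 lower in HPD) where chance gives 1074.4. The smallest p belonged to Glycam1, a mucin-like ligand of L-selectin, at 0.41 ± 0.085 (unadjusted p 0.000155; chromosome 7, 142455707 to 142455766, rn4). The potassium channel Kcnj5 stood at 0.79 ± 0.18, Dlk1 at 0.85 ± 0.20, the membrane protein Emp2 at 0.32 ± 0.072 and Thpol1 at 0.22 ± 0.05. Lower values were measured for Rassf4 at -0.30 ± 0.065, the glycoprotein Gpnmb at -0.48 ± 0.11, the ectonucleotidase Nt5e (CD73) at -0.32 ± 0.081, Slpi-ps1 at -0.19 ± 0.049 and Tceal9 at -0.57 ± 0.16. No list member passed over all genes. The count adjusted over the list alone was 1, the plasma cell gene Sdc1 at -0.36 ± 0.11 (unadjusted p 0.0037), named here after its values were seen. Among the lists that did not pass, the mean log2 differences above 0 were 0.057 for T cells, 0.043 for interferon response, 0.033 for cell cycle, 0.019 for oxidative phosphorylation, 0.011 for proteasome and 0.004 for amino acid and urea catabolism. Those below 0 were -0.12 for MHC class II presentation, -0.10 for glycolysis, -0.088 for PPAR targets, -0.079 for cytosolic heat shock proteins, -0.073 for apoptosis and p53, -0.069 for plasma cells and -0.066 for circadian clock. They were -0.062 for the ATF4 amino acid response, -0.04 for B cells, -0.036 for lipogenesis, -0.036 for fatty acid oxidation, -0.024 for basophils, mast cells and eosinophils, -0.024 for cholesterol synthesis and -0.013 for tricarboxylic acid cycle. RT1-Bb stood at -0.67 in the MHC class II list, and the other 14 members had a mean of -0.079. In the glycolysis list the arrays of Ldhb fall into 2 parts, with 1 HFD and 3 HPD arrays in the low one, and a mean without it was not taken. The lowest adjusted p among the lists that did not pass was 0.0612, for the interferon response. The mean, the median and the set test differed in sign for 2 lists, lipogenesis and the tricarboxylic acid cycle. Tests over whole arrays gave no call, with a lowest adjusted p of 0.353 by fry and 0.469 by exact permutation.

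Genes chosen beforehand for lipid, amino acid and stress metabolism and for cell identity are given here as differences HFD minus LFD, HPD minus LFD and HPD minus HFD, in that order, with one SE for the 3 and 6 arrays per diet. Cpt1a, which admits fatty acids to mitochondria, stood at 0.21, -0.094 and -0.30 (SE 0.11) and had an unadjusted p of 0.0163 by limma in HPD vs HFD. The uncoupling protein gene Ucp2 stood at -0.10, -0.17 and -0.068 (SE 0.10), fatty acid synthase (Fasn) at -0.091, -0.013 and 0.079 (SE 0.10) and Abca1 at 0.005, -0.20 and -0.20 (SE 0.10). Asparagine synthetase (Asns), a target of the amino acid response, stood at -0.062, -0.14 and -0.077 (SE 0.11), and the chaperones Hspa8 at 0.013, -0.12 and -0.13 (SE 0.13) and Hspa5 at 0.012, -0.076 and -0.089 (SE 0.13). The cytokine gene Il1b stood at 0.22, -0.37 and -0.59 (SE 0.34). Tnf was well above background on 3 of 6 LFD, 1 of 6 HFD and 1 of 6 HPD arrays, too few to give a difference. The glucocorticoid target Fkbp5 stood at -0.005, -0.061 and -0.056 (SE 0.14) and the clock gene Per1 at 0.045, -0.27 and -0.31 (SE 0.31). Among cell markers, Cd3e of T cells stood at -0.12, -0.015 and 0.11 (SE 0.21) and Cd79b of B cells at 0.061, 0.093 and 0.032 (SE 0.20). Cd14 of monocytes stood at 0.74, -0.42 and -1.17 (SE 0.37) and S100a9 of myeloid cells at 0.30, 0.38 and 0.088 (SE 0.32). Beta globin (Hbb) stood at 0.22, -0.82 and -1.04 (SE 0.53) and platelet factor 4 (Pf4) at -0.13, -0.76 and -0.64 (SE 0.55). Without LFD replicate 2, Pf4 stood at 0.32 in HFD vs LFD and -0.31 in HPD vs LFD. Without LFD replicate 6, Cd3e stood at -0.33 and -0.23 in these comparisons. Without HFD replicate 3, Per1 stood at -0.15 in HFD vs LFD and -0.12 in HPD vs HFD. None of these passed limma's test over all genes. Different probes disagreed in sign for Hspa8 in HFD vs LFD and for Fkbp5 in HPD vs HFD. Pdk4 is on the array but was not well above background on enough arrays to be tested.

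The HFD and HPD differences from LFD were also set side by side, since both use the same LFD arrays. Across 21488 genes, which are not independent replicates, they correlated at 0.42, and groups simulated with no effect against shared controls gave a mean of 0.50 (-0.24 to 0.85 in 100 simulations). The covariance was 0.006 against a simulated 0.0094, and 63.2% of the genes had the same sign against a simulated 67.1%. With the LFD arrays split 3 and 3 over 20 splits, the correlation averaged -0.15 (-0.56 to 0.12). Limma called 0 genes in both comparisons.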

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

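The counts of other splits for genes, the tests of the erythroid list with slide and with the background model, and the test of the RNA of one animal were chosen after the result was seen. In 456 groups of 6 arrays (named genes and lists by diet), 29 had 1 array far from the other 5. Chance gives about 1 in 20 groups, or 22.8, where arrays have equal spread. The values are those of the background model as planned, which damped some arrays of each diet. An array that was not damped could thus stand apart more readily. LFD replicate 2 was that array 8 times, with the platelet genes Pf4 at 2.56 and F13a1 at 2.37, Gsr at 1.28, Adipor1 at 0.65, Taldo1 at 0.34, Csf3r at 0.32, Oas1b at 0.29 and Steap4 at -0.11 (log2 ratios to the pool). LFD replicate 6 stood apart for the T cell gene Cd3e at -1.08 (the other 5 from 0.07 to 0.34) and for the means of the dendritic cell list at 0.16 and the fatty acid oxidation list at 0.13, and LFD replicate 1 for Slpi-ps1 at 0.055. In HFD, replicate 1 stood apart for Gsr at 0.48 and Dnajc3 at 0.64, replicate 2 for Fasn at 0.16, Arpc4 at -0.28 and Eomes at 0.26, replicate 3 for Per1 at 0.88 and Tnf, near background, at 0.083, replicate 4 for Acbd4 at -0.03 and Prf1 at -0.19, and replicate 5 for Ddit4 at -0.68. In HPD, replicate 7 stood apart for Klf6 at -0.64, Steap4 at 0.16 and the list of basophils, mast cells and eosinophils at 0.18, replicate 2 for Luc7l2 at 0.009 and Nt5e at -0.48, replicate 3 for Atf6 at 0.29 and replicate 4 for Rpl22 at 0.34.

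Erythroid markers were lower in HPD than in LFD by a list mean of -0.355 (SE 0.172, exact permutation p 0.0584, 6 arrays per diet). The background model is argued against as the cause, since the shift was -0.346 with the model fitted without marked spots. A slide difference cannot be told apart: the shift was -0.382 (SE 0.161) with slide as a block, but within 2 SE of 0 without LFD replicate 3 (-0.262, SE 0.153), HFD replicate 3 (-0.332, SE 0.183) or HPD replicate 5 (-0.261, SE 0.175), and it was -0.926 within slide 3 (1 against 1 array), -0.051 within slide 4 (2 against 2) and -0.214 without slide 1. The measure set beforehand left haemoglobin alone undecided. The 28 other members were lower too, with a mean of -0.321 (SE over members 0.059, 25 lower). They fell by less than that measure asked beside the 2 haemoglobin genes at -0.827. The members were read on the same arrays, so their SE is not one over animals. An effect of diet on the red cells or reticulocytes left in the preparation may also account for the lower erythroid markers, and no test here separates it from these.

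HFD replicates 1 and 6 were more alike than any other pair of the 18 arrays. The SD of their log2 difference was 0.182 with either background model. The lowest of the other pairs had 0.259 with the model fitted without marked spots and 0.25 with the model as planned. An alike cell make-up of the 2 samples cannot be told apart from other causes. The pair ranked 1, the closest of all pairs, for the 10 cell type list means (root mean square difference 0.112, median of all pairs 0.376), but a pair picked as the most alike over all genes tends to be close there in any case. RNA of one animal on both arrays stays open as well: among 42 genes whose arrays fall into 2 parts, the pair lay on opposite sides at 2, F13a1 and Bglap, where the closest other pair did at 5 and the median pair at 14 (at 1, 3 and 9 of 28 genes with the model as planned), and how many such differences one animal's RNA would give was not measured. An effect of the diet the 2 share was not tested.

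The 4 arrays of slide 1 lay at one end of the first component. A slide difference fits the values: with the background model fitted without marked spots and diet in the fit, limma called 547 genes for slide, and 1 of 100 regroupings of the arrays into slides of these sizes, the real one, gave as many (highest other 28). With all spots in the model the counts were 499 and 453. The background model as the cause is argued against, since 0 other arrays lay within the range of slide 1 on the first component when it was fitted without marked spots. Which of hybridisation, cell preparation or animals a slide stands for is not given in the sources used here, so whether the slide difference is technical or comes from the animals was not tested.

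For the counts of genes the other splits decide nothing, since with 0 genes called each split gives as many. Of 100 splits of the same arrays, the real one included, the count was thus 100 for HFD vs LFD (real 0, highest other 1), 100 for HPD vs LFD (real 0, highest other 836), 100 for HPD vs HFD (real 0, highest other 7), 100 for any diet (real 0, highest other 428) and 100 for genes called in both comparisons with LFD (real 0, highest other 0). Chance could not be excluded for the counts of lists. Of the 100 splits, 81 called as many lists as the real 4 for HFD vs LFD (highest other 14), 17 as many as 10 for HPD vs LFD (highest other 16) and 15 as many as 14 for HPD vs HFD (highest other 21). Over the 3 comparisons, 31 gave as many pathway lists as the real 16 (highest other 26) and 26 as many cell type lists as the real 12 (highest other 17). The other splits called a median of 6, 7 and 7 lists, so camera with a preset correlation calls several lists on these arrays with no diet behind the split. The split with 836 genes follows the slides in part. On one side were LFD replicates 4 and 5 and HPD replicates 2 and 4 (all of slide 4), LFD replicate 3 of slide 3 and LFD replicate 6 of slide 5. On the other were LFD replicates 1 and 2 of slide 1, HPD replicates 7, 1 and 3 of slide 2 and HPD replicate 5 of slide 3, so slide 3 was on both sides. The regrouping with 428 genes put LFD replicates 1 and 2 and HFD replicate 2 of slide 1 with HPD replicates 1 and 3 of slide 2 and HFD replicate 4 of slide 3, and its other 2 groups mixed the slides. The first side of the split with 836 genes also held the 4 LFD arrays damped by the background model, LFD replicates 3, 4, 5 and 6. HPD replicate 1, damped too, was on the other side. The regrouping with 428 genes put LFD replicates 3, 4 and 6 in 1 group. The splits were run with the model as planned only. Splits with many more genes than the real ones thus point to a structure of the values. Whether it lies in the samples or in the background model was not tested. With slide as a block limma called 0 genes for HPD vs LFD, and 1159 at an unadjusted p under 0.05.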

How the results depend on the processing

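The fits with the background model without marked spots, without marked spots altogether, without slide 1, with HFD replicates 1 and 6 averaged and the exact permutation of list means were chosen after the data were seen, the other 22 settings and the 18 fits without 1 array before. Limma called 0 genes for each comparison, for any diet and for both comparisons with LFD in all of them. No value of a named gene passed its threshold in 6861 comparisons of settings, and 30 changed sign by over 1 SD. Of the 28 called list shifts, 964 values stayed called, 177 did not and 7 turned in the direction of the set test. These values come from 23 alternative fits and the 18 fits without 1 array. They leave out the estimated correlation, fry and exact permutation, with which no call remained. They include a normalization that cannot move the log ratios, and the fit without the array with conflicting labels enters 2 times. The share that stayed called is thus no measure of stability. The list mean had the opposite sign in 9 of these 1148 values. Of other lists, 150 values were called in the direction that the set test had as planned, and calls in the opposite direction are not in that count. The 16 pathway calls were 0 with an estimated correlation, with fry and with exact permutation, and ranged from 8 (without HPD replicate 4) to 24 without 1 array. The 12 cell type calls were also 0 with each of those 3 tests, ranged from 9 to 14 without 1 array, and were 7 with array weights, 7 with the covariate T cells minus monocytes and 6 with the erythroid covariate. With scaling between arrays, interferon response HFD vs LFD stood at 0.083, interferon response HPD vs LFD at 0.211, T cells HFD vs LFD at 0.280 and T cells HPD vs LFD at 0.456. Without slide 1, interferon response HFD vs LFD stood at 0.025, interferon response HPD vs LFD at 0.10, T cells HFD vs LFD at 0.055, NK and cytotoxic cells HPD vs LFD at 0.086, oxidative phosphorylation HPD vs LFD at -0.028 and cytosolic ribosomal proteins HPD vs HFD at -0.008. With the covariate T cells minus monocytes, B cells HPD vs HFD stood at 0.127 and cytosolic ribosomal proteins HPD vs HFD at -0.014. For these changes the cause was not tested. With the background model fitted without marked spots, 0, 10 and 16 lists were called for HFD vs LFD, HPD vs LFD and HPD vs HFD (4, 10 and 14 as planned), the processed signals gave 0, 11 and 16, and the authors' table of log2 values 6, 15 and 17. The fit with a replicate block gave 4, 9 and 13 lists, with 0 genes called and 606, 1518 and 1062 at an unadjusted p under 0.05. It ended the call of immediate early genes HPD vs LFD, at -0.017. In HPD vs HFD it ended glucocorticoid response, at -0.118, and dendritic cells, at -0.085, and oxidative phosphorylation passed at 0.041. Arrays of one number correlated at -0.436 to 0.356 over 16 pairs (median 0.048, 6 over 0.1), and 3 of 17 arrays correlated best with their own number, so the arrays share only a number. Quantile normalization of the mean intensities of the 2 channels leaves the log ratios as they are, so it could move nothing and tests nothing. Cy5 alone, quantile-normalized between arrays, kept 0 of 4, 6 of 10 and 11 of 14 list calls. Signal over background limits which probes can be tested, as 10553 of 41012 were well above background on no array. Without a filter on dim probes 3, 9 and 12 lists were called, and 4, 9 and 12 over probes well above background on all 18 arrays. Without the filter T cells HFD vs LFD (-0.076), immediate early genes HPD vs LFD (-0.10), and glucocorticoid response (-0.146) and neutrophils (-0.093) HPD vs HFD were no longer called. With all 18 arrays required, immediate early genes HPD vs LFD (-0.102), and dendritic cells (-0.115) and neutrophils (-0.181) HPD vs HFD were not.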

Other observations

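The test of neighbouring genes was chosen after the result was seen, and so was the definition of the 2 parts. With the background model fitted without marked spots, 42 genes, 22 of them named, had arrays that fell into 2 parts with a gap of over 1 log2 unit and at least 2 arrays in each part. With the model as planned they were 28. Genes of the major histocompatibility complex on chromosome 20 (rn4) were among them. The class II beta chain gene RT1-Bb (4730533 to 4730583) had a mean log2 ratio of -4.90 on 5 arrays (HFD replicates 4 and 5, HPD replicates 1, 4 and 5) and 0.45 on the other 13, and its neighbour BX883043 (4751593 to 4751652) was low, at -2.12, on the same 5 and on LFD replicate 2. The class I gene RT1-CE3 (3552938 to 3553124) was low, at -1.65, on the same 5 arrays and on LFD replicate 4, and RT1-Aw2 on HFD replicate 4 and HPD replicate 4, at -3.85. In the NK receptor region of chromosome 4, Klrc3 (166941826 to 166941885) at -2.31 and Klri2 (167092275 to 167092842) at -1.72 were low on the same 5 arrays, LFD replicates 3 and 5, HFD replicate 4 and HPD replicates 2 and 4. The NK receptor gene Ly49s3 was low, at -2.0, on 4 LFD and 3 HFD arrays and 0 HPD arrays. Outside these regions, Adamts13, the protease of von Willebrand factor, was high, at 2.72, on LFD replicate 1 and HFD replicate 5 (-2.18 on the other 16), the fatty acid transporter Slc27a2 low, at -4.63, on LFD replicate 5, HFD replicates 2 and 5 and HPD replicate 7, and lactate dehydrogenase B (Ldhb) low, at -2.25, on 8 arrays. The chemokine Cxcl2 was low, at -2.77, on LFD replicates 2 and 4 and HPD replicates 7, 4 and 5.

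An inherited difference shared by neighbouring genes is a candidate explanation for part of these values, as a hypothesis. It asks that genes close to each other divide the arrays alike. The distance of 1 Mb and the measure were chosen with the divisions of these genes in view, among them the shared arrays of Klrc3 and Klri2 and of RT1-Bb and BX883043. The permutation p is therefore descriptive and rests on 4 pairs, and a test of this needs other animals. The 4 pairs of these genes within 1 Mb divided a mean of 1.75 arrays unlike, against 5.98 for the other pairs of the 36 genes with a position, and random placements of the genes gave as small a mean with a permutation p of 0.0006 (10000 placements). The pairs Klrc3 with Klri2 and Trpm2 with CO570092 divided all arrays alike, RT1-Bb and BX883043 all but 1, and Ly49s3 and Klri2 differed at 6. Trpm2, CO570092, Eif4b, Tmed9, AI511358 and Tuba1b-ps13 were low on the same arrays, LFD replicate 6 and HPD replicate 1, on which the background model also went wrong, and without such genes the mean over 3 pairs was 2.33 with a permutation p of 0.001. Of genes with several probes, 2 of 2 for Klrc3 and for Slc27a2 divided the arrays this way, but 1 of 2 for RT1-Bb, 1 of 3 for BX883043 and 1 of 4 for RT1-Aw2. A difference in the level of the whole RNA would move each probe that reads it, and whether the other probes of these 3 genes read the same RNA was not analysed here. For genes with 1 probe, a difference in RNA level and one in the probed sequence would look the same, and neighbouring probes that read one transcript would too.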
